A study of Drosophila melanogaster with 2 samples.

How the data were processed

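The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) for the transcription factor Irbp18 of Drosophila melanogaster, from the ENCODE collection. Per the labels, transgenic flies carried Irbp18 (also known as CG6272) fused to enhanced green fluorescent protein, chromatin came from whole embryos aged 0 to 24 h, and the fusion protein was precipitated with an antibody against GFP. Chromatin was sheared by sonication, with a size range given as 200 to 800, per the labels. The 2 samples are biological replicates 1 and 2 of 1 group, with the numbers taken from the labels. No control library was analysed here, and no second condition exists, so no comparison between groups was made.

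The authors deposited peak lists on the dm6 assembly. Each replicate had a thresholded list and a longer ranked list, and so did each of 2 pooled analyses made from both libraries, 1 of which the file names call conservative. The lists come from an irreproducible discovery rate (IDR) analysis, which ranks candidate peaks by how well they recur between sets. How reads were aligned and which program called the peaks are not given in the sources used here. The score column deposited by the authors is a whole number with no unit. In the ranked lists it equalled 125 times the negative binary logarithm of the global IDR, to within 1, with a ceiling of 1000. The signal value is the authors' own measure of each peak's height, in a scaling that is not given in the sources used here. It was therefore used only to describe, rank or filter peaks within a list. All thresholded peaks had a global IDR of at most 0.01 in the matching ranked list. In the conservative analysis 3499 candidates met that limit and 3454 were in the thresholded list. Of the 45 others, 42 lay outside the chromosome arms. Which list the pooled ranked files belong to was settled by exact matches of their rows. Further columns of the ranked lists hold values for single sets and were not used, since they could not be tied to a replicate by name.

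Read depth of the libraries is unknown, because the lists hold no read counts. Intervals on shares are exact Clopper-Pearson 95% intervals over sites. They cover counting error only, not differences between embryo collections, and neighbouring sites are not independent. P-values over sites likewise measure the sites of these lists and not the spread between animals.

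The main list was the conservative pooled list. This list, the gene lists, the motifs, the naming rule and the tests named below were chosen before the data were examined, except where stated. Its sites were taken at the summit and restricted to the arms X, 2L, 2R, 3L, 3R, 4 and Y of the release 6 reference sequence, on which all arm peaks ended within the arm lengths. Genes came from the Ensembl annotation BDGP6.54, release 115, without transposable elements and pseudogenes. A promoter site had its summit within 500 bp of an annotated transcription start. The other classes were assigned in the order 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. Promoter share, classes and replicate overlap were set against 1000 random placements of the summits within their arm, whose smallest p is 0.001 (0.002 for a two-sided test). Replicate sites were called shared when their summits lay within 100 bp. The arms were compared by exact binomial tests with their share of annotated starts and of sequenced length. The plan had named euchromatic length, for which no annotation was used here, so sequenced bases other than N took its place.

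The 14 motifs were counted on both strands within 50 bp of each summit and in a window of equal size centred 500 bp away, on a side drawn with a fixed seed. Shares were compared with the exact McNemar test. All words of 8 bases found in at least 10 windows were compared in the same way. Motif and signal rank were related by 100000 permutations, whose smallest p is 1e-05. Gene lists numbered 29. For each, protein-coding genes with a site within 500 bp of a start were compared with all other protein-coding genes by Fisher's exact test, two-sided. A symbol absent from the annotation was replaced by the current one where the reference gene table gave exactly 1. Adjusted p-values are Benjamini-Hochberg values over the motifs, words, lists, classes or arms tested together, with a threshold of 0.05.

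Several tests were added after the data had been seen. They are the share of promoter sites by signal value, the side of the start on which summits lie, GC content, the DRE and other motifs set against position and recurrence (only the CARE had been planned there), signal agreement within the middle 80% of sites, and the word scans split by position.

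Genes were named by a fixed rule. It took the 20 conservative sites with the highest signal value whose summit lay within 100 bp of a summit in both replicate lists, each named by its nearest protein-coding start. It took up to 4 genes with the highest signal value from each list described, and Irbp18, Xrp1 and crc whatever their values.

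Alternatives to the list, the replicates used, the site position, the distance to starts (200 and 1000 bp), the motif window (25 and 100 bp), the comparison windows, the gene assignment, the background and the sharing rule were fixed beforehand. The stricter IDR of 0.01 left all sites in place and therefore tested nothing. Placements matched on distance to starts and interval overlaps used 100 draws. Alternatives added after seeing the data were an IDR of up to 0.05 from the ranked list, sites at the top score of 1000, the strongest site of each run of summits less than 500 bp apart, removal of sites with a signal value under 10, and the choice of named sites from the other pooled list.

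The motif, word, gene list, promoter, overlap and signal agreement tests were run on simulated data. With a CARE planted in 25 of 3426 real flank windows, the motif test called the CARE and none of the other motifs, and with none planted it called no motif and no word. In 100 draws of random bound genes with 10 aminoacyl-tRNA synthetases forced to be bound, the list test called that list 100 times and made 7 false calls among all other lists. As the same 10 bound genes were set in every draw, the 100 calls were nearly certain and say nothing of smaller effects. The promoter test passed 0.05 in 3 of 50 sets of randomly placed sites. A simulated replicate sharing 1695 of 2748 sites gave 1699. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.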

Results

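Binding of Irbp18, a basic leucine zipper (bZIP) protein of the C/EBP type that pairs with the stress factors Xrp1 and crc (the fly ATF4), was mapped in whole embryos aged 0 to 24 h. The factor carried a GFP tag and was precipitated through it in 2 biological replicates of 1 group. The question the design addresses is where in the genome the tagged factor sits. Replicate 1 gave 2773 peaks and replicate 2 gave 2023, a ratio of 1.37. The conservative pooled analysis gave 3454 peaks and the other pooled analysis 3598, 1.04 times as many. Most peaks of the conservative list (76.1%) were 356 bp wide, and the widest was 485 bp. The signal value, the authors' own height of each peak, had a median of 121 in the conservative list and reached 2812. Of its peaks, 3426 lay on the chromosome arms and are the sites described here.

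The 3 strongest sites lay just upstream of Ugalt, CG14100 and mRpL41. The highest signal value, 2812, was at X:2703701-2704066 (dm6), 30 bp upstream of a start of Ugalt (FBgn0024994), a transporter of UDP-galactose. The next were at 3L:19590444-19590784, 98 bp upstream of CG14100 (FBgn0036889), with 2726, and at 2R:15217568-15217944, 117 bp upstream of mRpL41 (FBgn0034001), a protein of the mitochondrial ribosome, with 2639. In the replicate lists the Ugalt site had signal values of 1589 and 1241 (replicates 1 and 2) and the mRpL41 site 1599 and 1057. Of the 20 strongest sites found in both replicates, 15 were promoter sites, and 13 lay upstream of the nearest protein-coding start.

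Other promoters among these 20 belonged to Tcs5 (1985), the tubulin acetyltransferase gene Atat (1863), the Polycomb gene ph-p (1762), CG7601 (1713), CG5611 (1536), the chromodomain gene Chro (1519), the ribosome assembly factor gene eIF6 (1409), CenG1A (1392), the arginine methyltransferase gene Art3 (1390), mRpL23 (1372), CG8320 (1342) and GstE13 (1338), with signal values in parentheses. The other 5 lay farther than 500 bp from a start. Introns held the sites of CG11050 (2099, at 2L:6612544-6612890), Adf1 (1725) and CG32772 (1604), each within the named gene, and the site nearest to cbt (2064, at 2L:480915-481265) lay in an intron of ush. The site nearest to tara (1368, at 3R:16222326-16222646) was intergenic, 3167 bp upstream of its start. By the same rule the other pooled list gave the same 20 sites, to within 100 bp.

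At Irbp18 itself (FBgn0036126; 3L:11097446-11098186, minus strand), a site at 3L:11098275-11098426 had its summit 178 bp from the Irbp18 start. The start of APP-BP1 was nearer to it. Its signal value of 355 ranked 311 in the list, with 231 in replicate 1 and 111 in replicate 2. The lists do not separate the tagged transgene from the native gene. Neither partner gene had a site within 500 bp of a start. For Xrp1 (FBgn0261113; 3R:18914968-18926989) the best of 4 candidates at a start had a signal value of 64.9 and missed the IDR threshold. Its IDR, 1.304 as a negative decimal logarithm, was just within the limit of 0.05 used as an alternative. For crc (FBgn0000370; 2L:21310866-21319527) the ranked list held 0 candidates at a start. The sites nearest to Xrp1 were at 3R:18928491-18928846 and 3R:18928985-18929340, 4599 and 5093 bp from its nearest start, and belonged to the starts of Mpc1 and CG42613. Irbp, the fly Ku70 gene whose name the factor shares, had a promoter site with a signal value of 454, 78 bp from its start.

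Many sites recurred between the replicates. Of the 2748 replicate 1 sites on the arms, 1632 (59.4%, 95% interval 57.5 to 61.2) had a replicate 2 summit within 100 bp, and so did 81.5% of the 2003 replicate 2 sites (79.7 to 83.2). Random placement gave 0.305% and at most 0.728% of replicate 1 sites in 1000 draws, and 0.414% and at most 0.899% of replicate 2 sites (one-sided permutation p = 0.001, the smallest they can give). Of the 3426 conservative sites, 1617 (47.2%) lay within 100 bp of a site of both replicates, and 953 were in neither replicate list. Shared summits lay 16 bp apart in the median. Across these 1632 sites, which are not independent replicates, the signal values had a Spearman rho of 0.85 and a Pearson r on the log10 scale of 0.90 (permutation p = 1e-05 for each, the smallest 100000 permutations can give). Within the middle 80% of sites by replicate 1 signal, rho was 0.78.

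**Figure D1:**
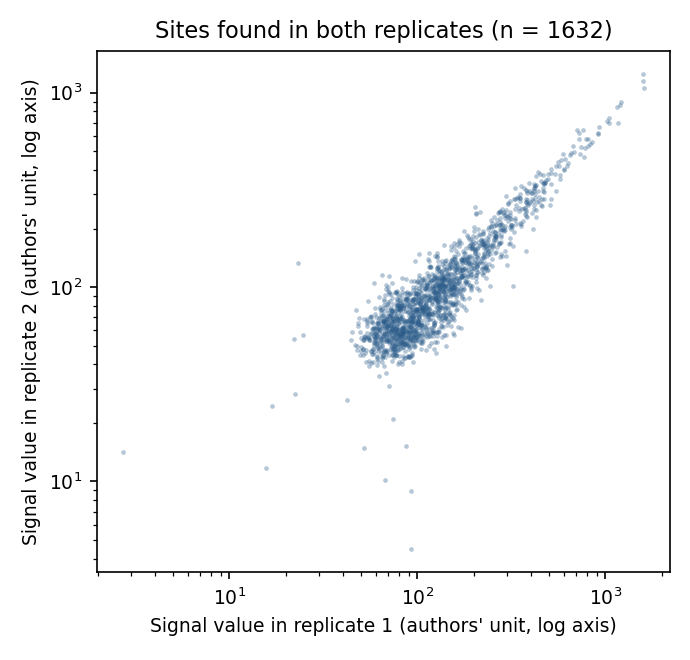
Signal value in replicate 2 against that in replicate 1, on log axes, for each site found in both lists (1 point per site, n = 1632). The points lie along a line, with a Spearman rho of 0.85.

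Conservative sites were concentrated at transcription starts. Of 3426 sites, 1899 (55.4%, 95% interval 53.7 to 57.1) had their summit within 500 bp of a start, against 13.4% ± 0.581 (SD over 1000 placements) by random placement, a 4.12-fold excess (one-sided permutation p = 0.001, the smallest they can give). Upstream summits made up 79.1% of these (1503 of 1899, with 392 downstream; exact binomial p = 7.36e-153), and the median position was 77 bp upstream. Introns held 944 sites (27.6% against 39.6% at random), intergenic sequence 429 (12.5% against 27.3%), coding exons 80 (2.34% against 13.1%) and 3' UTRs 29 (0.846% against 5.08%). Each of these 4 shares was below random (two-sided permutation test by random placement, adjusted p = 0.0028, the smallest reached). Since the classes exclude one another, the promoter excess by itself lowers the other shares. The ratios to random were 0.70 for introns, 0.46 for intergenic sequence, 0.18 for coding exons and 0.17 for 3' UTRs. Whether any class was short among the sites away from promoters was not tested. The replicate lists alone gave coding exon shares of 0.946% (replicate 1) and 0.699% (replicate 2). Over 10 alternatives that share ranged from 0.57% to 6.70%, and all 10 remained below random. In 5' UTRs beyond the promoter window, 15 sites (0.438% against 0.768%, permutation test, adjusted p = 0.0256) were found. That deficit was lost under 4 of 10 alternatives, among them replicate 2's list alone (permutation tests, adjusted p = 0.24; 0.00233 to 0.332 over all 10), and replicate 1's list alone gave 0.291%. Other exons held 30 sites and were not past the test (permutation test, adjusted p = 0.492), though 1 of 10 alternatives passed (permutation tests, adjusted p from 0.034 to 0.933).

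**Figure D2:**
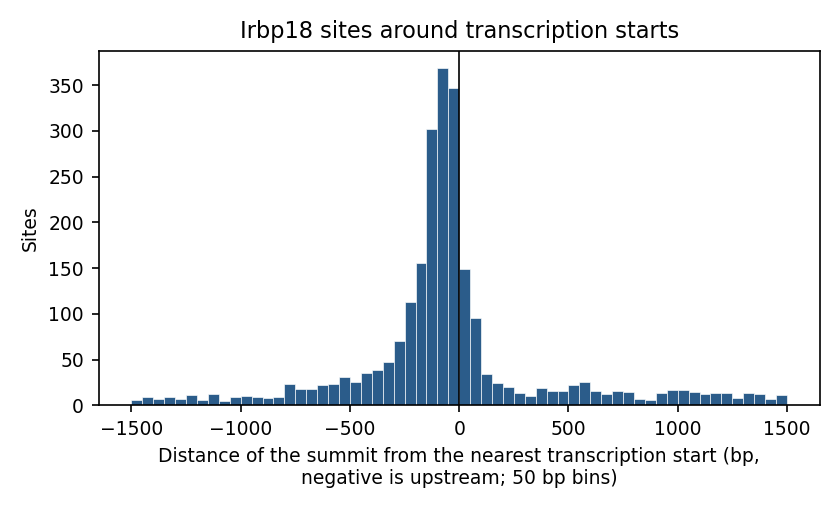
Number of conservative sites in bins of 50 bp by the distance of the summit from the nearest annotated transcription start (negative is upstream). The bars peak just upstream of the start, and the median of the 1899 sites within 500 bp is at -77 bp.

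Promoter sites were also the stronger ones. Their median signal value was 132 (quartiles 93.1 and 224), against 110 elsewhere (82.1 and 163). Among the strongest 25% of sites 66.5% were at promoters (570 of 857, 95% interval 63.2 to 69.7), and among the weakest 25% of sites 45.3% (388 of 856, 42.0 to 48.7), with an odds ratio of 2.39 (Fisher's exact p = 9.53e-19).

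By chromosome, the small chromosome 4 stood apart. It held 0 sites where its share of annotated starts predicted 25.7 (exact binomial test, adjusted p = 9.1e-11), and its best of 15 ranked candidates had an IDR of 0.134. Arm 2L, by comparison, had 22380 candidates. Whether chromosome 4 was filtered before peaks were called is not given in the sources used here, so the 0 may not reflect binding. The X chromosome held 646 sites, 1.15 times the number its starts predicted (exact binomial test, adjusted p = 0.000469), and 2R held 619, 0.876 times (adjusted p = 0.000469). By sequenced length 2R did not differ (0.98 times; exact binomial test, adjusted p = 0.582), while X was again above its share (1.10 times, adjusted p = 0.0186). With candidates of an IDR up to 0.05 the ratio for X was 0.951. Arms 2L, 3L and 3R had 637, 678 and 844 sites and did not pass the test by starts, and by length only 2L of these passed (1.08 times; exact binomial test, adjusted p = 0.0462). The Y chromosome had 2 sites, far below its share of length (85.2 predicted; exact binomial test, adjusted p = 2.1e-33) but not past the test by starts (7.48 predicted, adjusted p = 0.0726). Ranked candidates were sparse on Y too, 820 on 3.41 Mb against the 22380 on the 23.5 Mb of 2L. The deficit by length may therefore not reflect binding.

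Genes for cytosolic ribosomal proteins were the most often bound of the fixed lists. Of the 13968 protein-coding genes, 2343 (16.8%) had a site at a start. Each list was compared with all other protein-coding genes. The number of starts, the closeness of other genes' starts and expression, which was not measured, were not held equal. Among the 86 ribosomal protein genes, 49 had one (57.0%; odds ratio 6.69, 95% interval 4.26 to 10.6; Fisher's exact test, adjusted p = 8.29e-16), with the highest signal values at RpL32 (505), RpL34b (427), RpL7 (424) and RpS27 (342). Of the 20 cytosolic aminoacyl-tRNA synthetase genes, whose enzymes charge tRNAs, 10 were bound (odds ratio 4.98, 1.86 to 13.3; adjusted p = 0.00362 by Fisher's exact test), led by GluProRS (507), SerRS (386), IleRS (289) and ThrRS (259). Replicate 2's list alone and the sites at the top score did not call this list (odds ratios 2.70 and 3.29; Fisher's exact test, adjusted p = 0.197 and 0.0506, and 0.00149 to 0.197 over 12 alternatives).

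Mitochondrial ribosomal protein genes held some of the strongest sites of the genome, and 23 of 73 were bound (31.5%; odds ratio 2.29, 1.33 to 3.84; Fisher's exact test, adjusted p = 0.00899). Their top sites were those of mRpL41 (2639), mRpS23 (1392), mRpS10 (1390) and mRpL23 (1372). The sites of mRpS23 and mRpS10 are the ones named above for CenG1A and Art3, since the starts lie close together. With each site given only to its nearest start, this list was not called (odds ratio 1.28; Fisher's exact test, adjusted p = 0.657, and 0.000287 to 0.657 over 12 alternatives), nor was it among genes with a ranked candidate.

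The lists of DNA repair, the unfolded protein response, autophagy and glycolysis were bound above the genome's rate too. DNA repair and checkpoint genes were bound in 12 of 25 cases (odds ratio 4.6, 1.91 to 10.9; Fisher's exact test, adjusted p = 0.00211), among them the ATR kinase gene mei-41 (475), Irbp (454), nbs of the double-strand break complex (241) and the photolyase gene phr6-4 (194). For the unfolded protein response of the endoplasmic reticulum, 8 of 16 genes were bound (odds ratio 4.97, 1.63 to 15.2; Fisher's exact test, adjusted p = 0.00899), with Hrd3 (468), the transcription factor gene Xbp1 (389), Sec61alpha (303) and Herp (245) highest. That call was not made with nearest starts only or with replicate 2's list alone (Fisher's exact test, adjusted p = 0.135 and 0.0902, and 0.00268 to 0.135 over 12 alternatives). Autophagy genes were bound in 9 of 24 cases (odds ratio 2.98, 1.15 to 7.29; Fisher's exact test, adjusted p = 0.0393), led by Atg17 (453), Atg2 (316), Atg7 (287) and Atg18a (285). The autophagy call ended under 5 of 12 alternatives (Fisher's exact test, adjusted p from 0.0149 to 0.426). Of 13 glycolysis genes, 7 were bound (odds ratio 5.80, 1.67 to 20.9; Fisher's exact test, adjusted p = 0.00899), including Eno (533), Pgk (285), Ldh (253) and Hex-A (137). A start distance of 200 bp ended the glycolysis call (Fisher's exact test, adjusted p = 0.246, and 0.00132 to 0.246 over 12 alternatives), and replicate 2's list alone gave an odds ratio of 9.46.

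The integrated stress response list, which holds the reported kinds of targets of ATF4, had 8 of 22 genes bound (36.4%; odds ratio 2.84, 1.03 to 7.27) and missed the threshold (Fisher's exact test, adjusted p = 0.0628). The highest signal values were at Sesn (910), which encodes sestrin, the phosphoserine phosphatase gene aay (597), Ldh (253) and the asparagine synthetase gene AsnS (244). The other pooled list, the replicate 1 list alone and candidates of an IDR up to 0.05 did call it (Fisher's exact test, adjusted p = 0.0291, 0.0386 and 0.0468, and 0.0291 to 0.869 over 12 alternatives). Of the 20 other bZIP factor genes, 6 were bound, including Atf3 (660), Xbp1 (389), CrebB (147) and cnc (130), with no call (adjusted p = 0.313 by Fisher's exact test).

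Chemoreceptor genes were the opposite extreme. None of 179 odorant, gustatory and ionotropic receptor genes had a site (upper 95% bound of the odds ratio 0.102; Fisher's exact test, adjusted p = 1.29e-13). Of the histone genes only the variant gene His2Av (197) did, 0.87% of the list (odds ratio 0.0431, 0.00108 to 0.245; Fisher's exact test, adjusted p = 2.25e-07), with an odds ratio of 0.0703 in replicate 2's list alone. Most histone genes are copies in a tandem array, where placing reads is uncertain, and among genes with a ranked candidate the odds ratio was 1.17 (Fisher's exact test, adjusted p = 1, and 7.95e-10 to 1 over 12 alternatives).

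The other 18 lists were not called. The tissue lists were fixed beforehand, and a gene on such a list need not be specific to the tissue named. Bound genes numbered 3 of 16 on the list for muscle (Msp300, sls and how), 1 of 16 for neurons (elav), 1 of 8 for glia (moody), 1 of 16 for hemocytes and fat body (ush), 1 of 13 for gut (tin), 3 of 13 for epidermis and trachea (shg, crb and trh) and 1 of 9 for germline (gcl). Embryonic patterning factors had 2 of 31 bound, bcd (133) and wg (93.7). The remaining counts were 3 of 35 glutathione S-transferases, 5 of 18 redox and pentose phosphate genes, 3 of 18 apoptosis and cell competition genes, 7 of 40 proteasome subunits, 12 of 44 translation initiation factors, 16 of 84 oxidative phosphorylation genes, 4 of 19 heat shock proteins, 4 of 18 ribosome biogenesis genes, 5 of 22 cell cycle genes and 1 of 3 for Irbp18 and its partners. The lowest adjusted p among these 18 was 0.182 (Fisher's exact test).

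**Figure D3:**
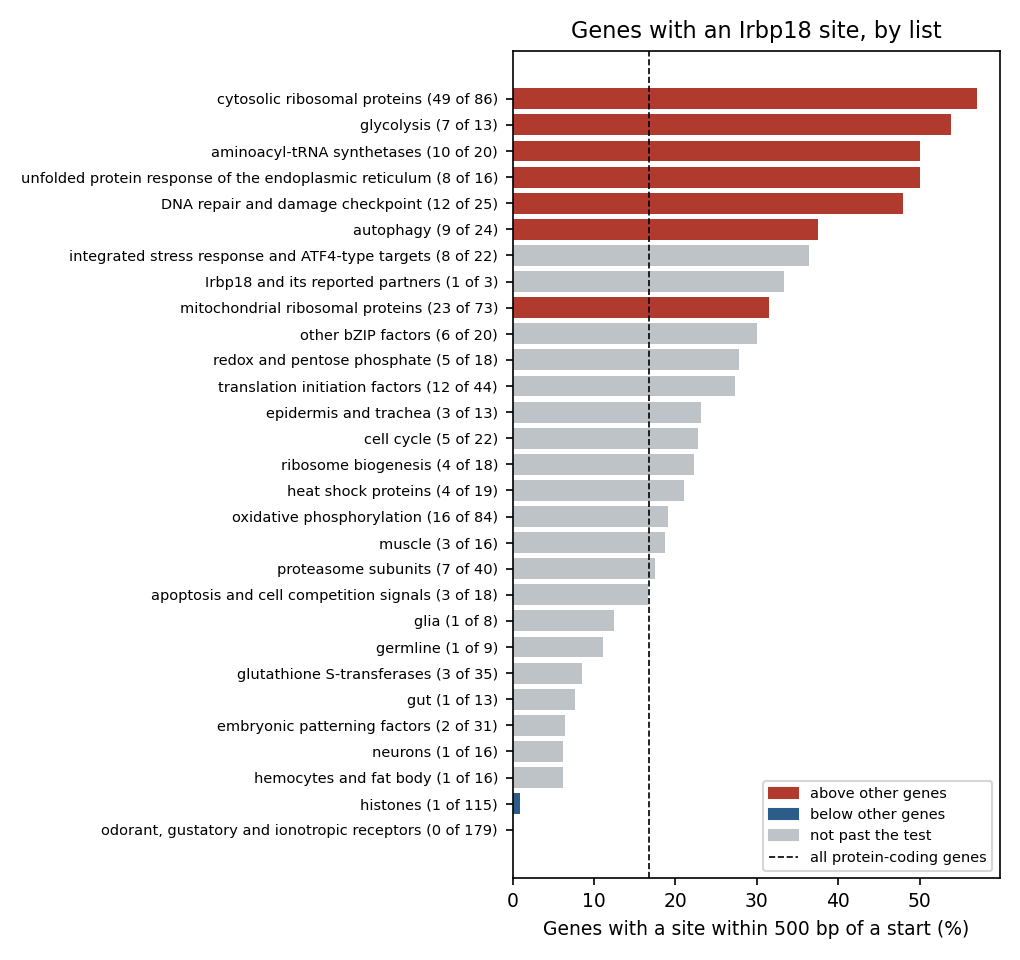
Share of the genes of each list with a site within 500 bp of a start (bars, with bound and total genes beside each name), against the 16.8% of all protein-coding genes (dashed line). Cytosolic ribosomal protein genes lead at 57.0%, and the receptor list is at 0.

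The DNA sequence expected of a C/EBP and ATF4 pair was not enriched at the summits. The composite site of both families (CARE, TGATGYAA) occurred within 50 bp of 20 of 3426 summits (0.584%, 95% interval 0.357 to 0.9) and in 16 windows 500 bp away (exact McNemar test, adjusted p = 0.786). The C/EBP palindrome TTGCGCAA was found at 6 summits against 7 flanks, the PAR site TTACGTAA at 6 against 3, the CRE palindrome TGACGTCA at 4 against 10, and the AP-1 site TGASTCA at 32 against 31, none past the test (lowest adjusted p = 0.279, exact McNemar test). Some of these small counts changed direction in the list of a single replicate, with ratios of 2.5 for the C/EBP palindrome (replicate 2), 1.33 for the CRE palindrome (replicate 1), and 0.724 and 0.952 for the AP-1 site (replicates 1 and 2). The relaxed C/EBP site TTRCNNAA was modestly more frequent at summits, 16.7% against 13.5% (572 against 464 windows; exact McNemar test, adjusted p = 0.000723). Summit windows also had a lower GC content than flanks (38.1% against 43.7%), and whether composition alone gives the relaxed site's excess was not tested. With candidates of an IDR up to 0.05 that excess was gone (ratio 0.986; exact McNemar test, adjusted p = 1, and 6.74e-06 to 1 over 12 alternatives). The other 11 alternatives, among them the windows matched on distance to starts, kept the excess past the threshold.

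Instead, the DNA replication-related element (DRE, TATCGATA), a promoter motif of housekeeping genes, was 11.9 times as frequent at summits as in flanks. It occurred at 119 summits (3.47%, 95% interval 2.89 to 4.14) and in 10 flanks (exact McNemar test, adjusted p = 1.1e-23). Among promoter sites 118 of 1899 (6.21%) held it, and elsewhere 1 of 1527. Windows matched on distance to starts held it in 0.963% of cases, a ratio of 3.61, and replicate 2's list alone gave a ratio over flanks of 7.63. The core promoter words Motif 1 (26 summits against 5 flanks; exact McNemar test, adjusted p = 0.000538) and the TATA box (6.8% against 3.39%; adjusted p = 9.24e-10) were also enriched over flanks, but not over the matched windows (exact McNemar test, adjusted p = 0.888 and 0.242, the highest of their alternatives). Replicate 1's list alone put Motif 1 at 9.33 times its flank share, against 5.2 in the conservative list. The CTCF core was at 5.69% of summits and 3.79% of flanks (exact McNemar test, adjusted p = 0.000633), and replicate 1's list alone did not call it (adjusted p = 0.0513, and 1.52e-09 to 0.0513 over 12 alternatives). The GAGA element (0.817% against 2.66%) and the CA repeat (0.876% against 3.27%) were depleted (adjusted p = 2.03e-08 and 4.93e-12 by exact McNemar test). The E-box and the Zelda site were not called (adjusted p = 0.103 and 1 by exact McNemar test), although replicate 2's list alone and the sites at the top score called the E-box depleted (exact McNemar test, adjusted p = 0.0154 and 0.00813, and 0.00813 to 1 over 12 alternatives).

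**Figure D4:**
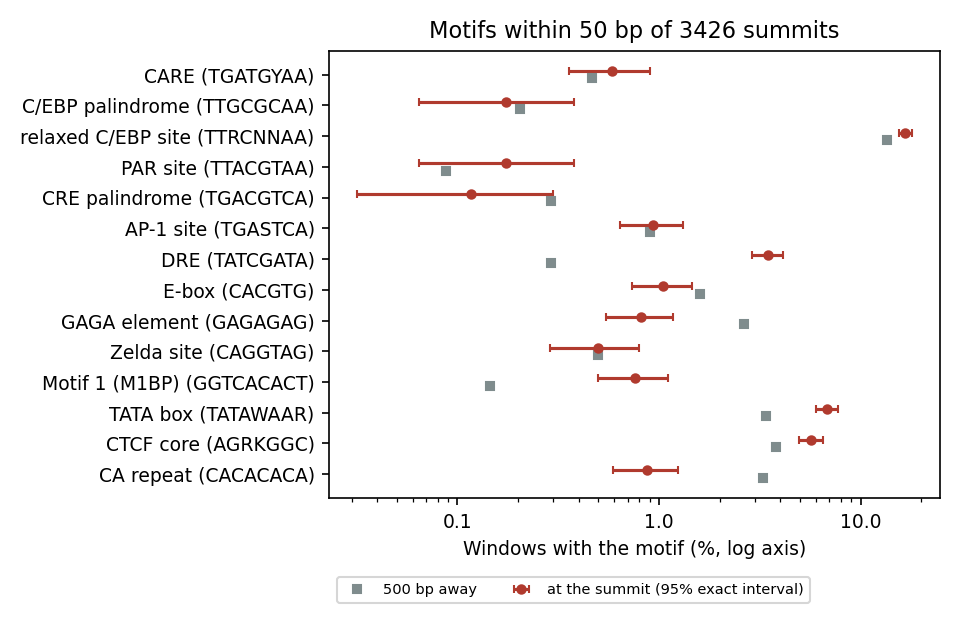
Share of windows with each of 14 motifs (log axis, %), at the summit (circles with exact 95% intervals) and 500 bp away (squares), for 3426 sites. The DRE stands at 3.47% at summits and 0.292% in flanks, while the CARE interval includes its flank share.

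A scan of all words of 8 bases, with no motif assumed, gave the same leading sequence. Of 24223 words, 376 passed (exact McNemar test, adjusted p under the threshold), 290 of them higher at summits. The leading words were ATCGATAG (142 summits against 14 flanks) and TATCGATA, and 39 of the 290 contained the core TATCG of the DRE. A further 89 consisted of A and T alone. On either strand, 7 of the 290 held TTGC, as in the C/EBP palindrome, or TGATG, as in the CARE. ATTGCATA was among them (41 summits against 12 flanks; exact McNemar test, adjusted p = 0.00916). A word with so short a part need not be a site of either family. GC content was 38.1% ± 11.6 (SD, n = 3426 sites) within 50 bp of summits and 43.7% ± 10.6 in flanks, lower at 64.9% of sites (permutation p = 1e-05, the smallest 100000 permutations can give).

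The CARE did not mark stronger sites. The mean signal rank of its 20 sites differed from that of all other sites by -5.38 percentile points (permutation p = 0.41). Sites at the top score gave -15.6 points (permutation p = 0.0246), and candidates of an IDR up to 0.05 turned the difference to 3.26 points (permutation p = 0.548). In successive sets of 25% of the list, from strongest to weakest, 2, 5, 11 and 2 sites held it. The DRE likewise did not mark the strongest sites, with 2.22%, 4.91%, 5.02% and 1.75% in the same sets. The CARE was found at 7 of 1899 promoter sites and 13 of 1527 sites elsewhere (odds ratio 0.431, 95% interval 0.145 to 1.17; Fisher's exact p = 0.0735), a difference that the other pooled list put past the threshold (Fisher's exact p = 0.0119, and 0.0119 to 1 over 12 alternatives). Promoters with a CARE site belonged to 11 genes, and none of the 29 gene lists was called for them by Fisher's exact test (0 at an unadjusted p under 0.05). So few genes left the test little power. For the integrated stress response list, with 0 bound, the upper 95% bound of the odds ratio was 270. The absence of calls therefore decides nothing.

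Sites found in 1 replicate only, 1116 in replicate 1 and 371 in replicate 2, resembled the shared ones in position. Promoter sites made up 60.2% of the 1632 shared and 57.8% of the 1487 single-replicate sites (odds ratio 1.10, 95% interval 0.955 to 1.28; Fisher's exact p = 0.177). With a start distance of 1000 bp the difference passed the threshold (Fisher's exact p = 0.0207), and with 200 bp its sign turned (Fisher's exact p = 0.693). The CARE was at 6 shared and 13 single-replicate sites (Fisher's exact p = 0.104), and the DRE at 3.25% and 4.91% (Fisher's exact p = 0.0225), a difference lost in windows of 25 bp (Fisher's exact p = 0.38).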

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

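Both results here are listed because they lie outside the sites that the report's comparisons rest on. The second set enters the report only through the alternative with an IDR up to 0.05. Each count is above the 3 that a count of 0 allows, a limit that tests nothing at this size. All tests in this part were chosen after the result was seen. No biological explanation was tested for them.

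The conservative list held 28 peaks outside the chromosome arms, all on 25 sequences assigned to X but not placed on it. Their density, 27.9 per Mb (exact Poisson 95% interval 18.5 to 40.3), lay close to the 27.5 per Mb of the X arm, and their signal values had a median of 117 and reached 904.

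Between an IDR of 0.01 and 0.05 the ranked conservative list held a further 2244 candidates on the arms. They differed from the sites described in the report. Promoters held 30.4% of them (682, 95% interval 28.5 to 32.3) against 55.4% of the sites (odds ratio 2.85, Fisher's exact p = 6.93e-78), coding exons held 13.4% (300), and the DRE was at 1.52% of their summits. GC content was 49.0% ± 11.3 (SD, n = 2244 candidates) and the relaxed C/EBP site was at 9.49%. Of these candidates 0.98% had a thresholded summit within 500 bp.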

How the results depend on the processing

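Of 144 alternative values for results that answer a comparison, 132 were counted as unchanged. For tests this meant the same direction and the same side of the threshold. For results that are counts, such as the number of lists called, it meant a change within a fixed factor, whichever members made up the count. The 10 values for the CARE gene lists were 0 throughout, which the few genes with a CARE site made likely. The promoter share ranged from 43.1% to 64.8% and passed the placement test under all 10 alternatives, the replicate overlap ranged from 50.1% to 61.9% under 6, and the DRE ratio from 3.61 to 17.3 under 12. The IDR of 0.01 is not counted, as it moved no site. For the CARE no alternative passed, with ratios from 0.769 (matched windows, below 1) to 2.13. Leaving out a replicate gave promoter shares of 58.1% and 60.5%. Under the alternatives added after seeing the data, an IDR of up to 0.05 raised the number of sites to 5673, turned the relaxed C/EBP ratio to 0.986 and the CARE rank difference to 3.26 percentile points, put 5 arms past the threshold and brought X to 0.951 times its expectation. These shifts come with the candidates added, 2244 of which lie between an IDR of 0.01 and 0.05. Sites at the top score put the CARE rank difference (-15.6) and its promoter odds ratio (0.295) past the threshold. Among the alternatives fixed beforehand, the other pooled list put that odds ratio at 0.324 and 5 arms past the threshold, words of 6 bases gave 880 calls, and start distances of 200 and 1000 bp moved the shared minus single promoter difference to -0.726 and 3.91 percentage points. Among genes with a ranked candidate the histone odds ratio was 1.17. The cause was not tested. Of 348 values for single gene lists, 332 kept their call. The cytosolic ribosomal protein, DNA repair and receptor lists were called under all 12. For Motif 1 in 25 bp windows no ratio could be formed, as its flanks held 0 copies. No paired analysis was possible because there is 1 group. Depth, which is unknown here, limits which weak sites could be called.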

Other observations

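The tests of the first paragraphs, on GC content and words, were all chosen after the result was seen.

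Sites away from starts carried a flanking word. In windows of 100 bp on each side of their summits, 58 of 21979 words of 8 bases passed (exact McNemar test, adjusted p under 0.05), 55 of them higher than in flanks, and 27 of these held CAGTG or its complement. The leading word was CACTGAGA (70 sites against 5 flanks). The core CAGTG was most frequent near 75 bp on either side of the summit, at 9.5% and 8.97% of the 1527 sites, and less so at the summit (5.3%) or 500 bp away (3.34%). Within 12 bp of the positions 75 bp away, 17.2% of these sites held it, against 6.61% for the positions 500 bp away (ratio 2.60). Promoter sites had 13.8% and 9.58% (ratio 1.44). The core and the distance were both picked from these sites, so the ratios describe them and test nothing. Words with this core also passed in the windows of 50 bp around all summits, among them CACAGTGG (63 against 15 flanks) and CACTGTGC (67 against 19). No protein was assigned to the core.

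GC content fell as signal rose. Within 50 bp of the summit it was 31.5% ± 8.75 (SD, n = 857 sites) in the strongest 25% of sites, then 36.7% ± 10.1 (n = 856), 38.7% ± 11.1 (n = 857) and 45.4% ± 11.7 (n = 856) in the weaker sets. The relation held across all 3426 sites (Spearman rho -0.43, permutation p = 0.0001, the smallest 10000 permutations can give), and was of like size at promoters (-0.44) and elsewhere (-0.44). The 20 named sites had a median of 28.2%, and none held a DRE or a CARE. No control library was analysed here to set this beside.

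Promoter and distal sites differed in their words. Within 50 bp of the summits of the 1899 promoter sites 275 words of 8 bases were higher at summits, 45 with the DRE core, and at the 1527 other sites 7 were, 5 of them A and T alone and none with the DRE core. These counts are not on equal terms. More words were tested at promoters (13356 against 9329). Within 25 bp of summits GC content was alike (37.7% at promoters, 37.9% elsewhere). At 500 bp to either side it was 45.9% and 45.1% for promoter sites, against 41.3% and 41.5% elsewhere. The leading word elsewhere was AGATGGCG (23 summits against 1 flank), which contains the CTCF core AGRKGGC. Among the strongest 25% of sites 324 words were higher, but only 5 held the DRE core, 112 were A and T alone, and the leading word was ATATTTAA (70 sites against 9 flanks). The CTCF core was at 5.53% of promoter sites and 5.89% of the others (Fisher's exact p = 0.657).

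The patterns weighed below were picked from these data. The 3 tests of the CARE, on its density around the summit, on the strongest 25% of sites and on candidates under the threshold, were set in their present form only after the result was seen, and the other tests before their result, though the numbers of weak sites and of overlapping neighbours in the list were then known.

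The DRE at summits was first set against position. Windows at the same distance from random starts held it in 1.07% of cases and at most 1.72% in 1000 draws, against 3.47% observed, which argues against promoter position alone. Base composition is argued against as well, since 200 dinucleotide shuffles of the windows gave at most 0.35%. What stays open is whether the tagged factor, its partners or the open chromatin of DRE promoters places the sites there, and no biological explanation was tested.

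The lack of CARE enrichment at summits was tested in 3 ways. Its density within 250 bp of summits was 1.02 times that 500 to 1000 bp away (95% interval 0.783 to 1.32). These values argue against a rise near summits beyond that range. With 90 copies within 250 bp a smaller rise was not excluded, so misplaced summits at some sites stay possible. Loss through the IDR threshold and dilution by weak sites stay open. The 126287 candidates that missed the threshold held it in 0.493% of cases, a difference of -0.0905 percentage points from the sites (95% interval -0.348 to 0.168). In all, 623 of these candidates held it. Over so many candidates, the upper bound of the difference amounts to 212 CARE sites beyond what the sites' own rate predicts. The limit set for this test was the 20 in the list, which so large a number of candidates could hardly meet. The test therefore decides nothing. Of the strongest 25% of sites 2 held it (0.233%, exact 95% interval 0.0283 to 0.84), as did 2 of their flanks (exact 95% interval of the ratio 0.0725 to 13.8), too few to decide. Binding through another sequence or another protein stays open too, as an untested hypothesis.

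A group of 75 sites (2.19% of the list) had signal values under 10, with a median of 5.9, yet 51 of them carried the top score. Of these 75 sites 98.7% (74, exact 95% interval 92.8 to 99.97) overlapped a stronger site of the same list, against 3.1% of the other 3351, so they may be shoulders of stronger sites. Repeated sequence is argued against, since the median soft-masked share (11.8%) differed from that of the other sites (17.4%) by -5.62 percentage points.

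A hypothesis formed from the pairs of close starts among the strongest sites was that bound promoters tend to be divergent. Of 1706 genes whose start was the nearest to a site, 944 (55.3%) had an opposite-strand protein-coding start within 1000 bp upstream, against 33.5% of the other 12262. The odds ratio of 2.46 (95% interval 2.22 to 2.73, Fisher's exact p = 2.19e-66) shows that a site and a divergent start went together across genes. A gene with more annotated starts has more chances of both, and the number of starts was not held equal. No sites were placed at random among promoters, so chance placement among them was not excluded. The result is consistent with a preference for divergent promoters, which may reflect their expression in many cells, a property not measured here.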
